A study of Mus musculus with 4 samples.

How the data were processed

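The series holds 4 single-cell RNA-seq libraries of liver cells from male C57BL/6J mice, 1 library for each combination of diet and week. Mice received normal chow or the FAT-MASH regimen, which combines a Western diet, sugar water and weekly low-dose carbon tetrachloride, for 12 or 24 weeks. Per the labels' protocols, livers were kept overnight on ice, digested with collagenase and DNase, and enriched for non-parenchymal cells on a Percoll gradient before 10x Genomics 5′ library preparation. This enrichment sets the shares of cell classes, so a share describes the suspension and not the liver. Some hepatocytes remained in every library.

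The deposited matrices held raw UMI counts (unique molecular identifiers, 1 per captured molecule) for each gene and barcode. The authors made them with Cell Ranger, version 5.0.1 for 3 libraries and version 4 for the 12-week MASH library, per the file headers. The submitters' processing notes name the builds mm10 and GRCh38, without saying what each was used for. How barcodes were called as cells is not given in the sources used here. Of the 32285 genes in the deposited gene lists, 32158 (99.61%) had their identifier in the mouse annotation GENCODE M21, from which gene positions on GRCm38 were taken. The deposited features also included hashtag antibodies, 6 in each 12-week library and 8 in each 24-week one. Those with at least 1% of a library's hashtag UMIs were used: 1 to 3 in 12-week chow, 4 to 6 in 12-week MASH and 1 to 8 in both 24-week libraries. The labels do not say what a hashtag marks, so hashtags were never treated as animals or replicates.

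The matrices held 19442 (chow, 12 weeks), 737280 (MASH, 12 weeks), 27670 (chow, 24 weeks) and 20874 (MASH, 24 weeks) barcodes. The 12-week MASH matrix contained every barcode of the kit, and the deposited list of 19014 barcodes did not match its columns, so its cells were taken as the 19091 columns with at least 500 UMIs. In the other matrices every column already had 500 UMIs or more. Cells were kept with at least 300 genes, at least 500 UMIs and at most 15% mitochondrial UMIs. After this filter 18436, 17225, 27291 and 19953 cells remained, in the same order of libraries.

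Doublets were called per library with Scrublet as implemented in scanpy 1.11.5. The automatic threshold was used where it marked between 0.5% and 25% of cells, and otherwise the highest scores at a rate of 0.8% per 1000 cells. It marked 25.8% of the 24-week chow library, so the expected rate of 21.8% applied there. The removed shares were 11.2%, 18.7%, 21.8% and 12.4%. Cells carrying several hashtags, found from a mixture of 2 normal distributions per hashtag, made up 20.3%, 26.7%, 22.8% and 23.9% of cells passing the filter, and Scrublet removed 26.0%, 35.7%, 52.8% and 35.3% of them. Many such cells were therefore kept.

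The kept cells numbered 16363, 14001, 21333 and 17476 with median depths of 1980, 2974, 2065 and 3166 UMIs. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were used without mitochondrial, ribosomal protein, immunoglobulin variable and T cell receptor variable genes and without the genes of the fixed lists. Clustering used 30 principal components, 15 neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) on all libraries together, with no batch integration. Fold values and intervals were computed with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, the neighbour search with scikit-learn 1.9.0 and the plots with matplotlib 3.10.9, under Python 3.11.15.

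Clusters were named from 16 marker sets. A cluster took the class with the highest mean marker z-score if at least 3 of its markers were seen in 10% of cells. Because names rest on markers, classes are written as "-like" cells. Stellate-like stands for stellate cells or fibroblasts, NK-like for NK cells or ILC1, and monocyte-like for monocytes or macrophages. Each of these pairs shared 1 marker set and was not told apart. A set of limits was added after the clusters were seen. A score under 0.5 left a cluster unnamed, as did a median depth below the library's median divided by 3 with no marker among the top 10 genes. A second class with a score above 1 and over 80% of its markers detected made it mixed. Mixed clusters (endothelial with T cell markers, B cell with hepatocyte markers) held 9.93%, 4.32%, 4.28% and 1.70% of kept cells, and unnamed clusters 6.20%, 7.23%, 3.21% and 2.44%. This left 15 classes. One of them, cluster 11, is reported by its number. Its cells scored highest on the Kupffer cell set, of which only 2 markers were detected, and carried 9 of the 10 monocyte and macrophage markers.

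Each comparison sets 1 library against 1, which leaves no residual degrees of freedom, and no p-value was computed. A model of diet and week together, with 1 residual degree of freedom, was not fitted. For a class, UMIs were summed over its cells in each library and divided by the class total, giving CPM. MASH was compared with chow of the same week. A ratio of CPM has an exact conditional binomial interval, a CPM value an exact Poisson interval and a share of cells an exact Clopper-Pearson interval, all at 95%. Where 1 library had 0 UMIs, the fold is a lower bound against 3 counts. Shares of cells with a Plaur UMI were also computed after thinning each cell to 1000 UMIs, with shallower cells left out.

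In the 10 classes with at least 100 cells in every library, genes were counted that were at least 2-fold higher, or at least 2-fold lower, in MASH at both weeks. Genes entered with at least 30 UMIs and 20 CPM in the higher library at each week. The number that independent lists would share is given beside the observed one. Named genes are, in the 6 largest classes, the 5 higher and 5 lower genes with the largest smaller-of-both-weeks log2 ratio (0.5 UMI added for ranking). Markers, mitochondrial, ribosomal, immunoglobulin and T cell receptor variable and predicted genes were left out, as were genes below 10% of their level in the highest class of that library, which are called open to RNA of other cells. For cluster 11 and the monocyte-like, conventional dendritic-like and stellate-like cells the same ranking was applied after the data were seen.

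For each of 15 gene lists, the median log2 CPM ratio over members with at least 10 UMIs was taken in the classes the list concerns, with an interval from 1000 Poisson draws around the members' own counts. A member at 0 UMIs in 1 library counts as undecided where its bound against 3 counts is under 2-fold, and the median is also given with such members at their bounds. The percentile of a median among 10000 random lists of equal size, matched on expression, describes these libraries only. The lists were uPAR and plasminogen activation, lipid- and scar-associated macrophage genes, senescence, inflammatory cytokines, fibrillar matrix, T cell activation, naive and central memory T cells, MHC class II, sinusoidal identity, endothelial capillarisation, cell cycle, interferon response, dissociation and storage stress, cholesterol handling and oxidative stress. Values of some single members are not reported here. The lists, markers, filters, gene rule and first group of alternatives were fixed before the data were examined.

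The fold rule was tested on simulated counts with 200 changed genes per class, 50 at each fold size. In T-cell-like cells, with 5405 genes, it recovered 16 of 50 genes at 2-fold and all 50 at each of 3-, 4- and 8-fold, and in cluster 11, with 2791 genes, 9, 34, 44 and 48 of 50. No unchanged gene passed in the 10 compared classes and 4 passed in cluster 11. The simulated counts varied by counting error only, so these numbers do not cover differences between libraries. For 200 unchanged lists of 12 genes in T-cell-like cells at 12 weeks the median percentile was 48.9, and a list raised 2-fold reached the percentile of 100.

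That first group consisted of a stricter filter (500 genes, 1000 UMIs, 10% mitochondrial UMIs), no doublet removal, Leiden resolution 0.5, scaling by edgeR 4.0.16 TMM factors, totals without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, equal weight for every cell, and gene minimums of 10 UMIs with no CPM minimum or of 100 UMIs. After the data were seen, runs were added with single-hashtag cells only, with other denominators, with the 24-week chow library split into hashtags 1 to 4 and 5 to 8, and for the comparison of weeks.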

Results

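The data comprised 4 libraries of liver non-parenchymal cells, 1 each from mice on chow and on the FAT-MASH regimen at 12 and 24 weeks. FAT-MASH is a mouse model of metabolic dysfunction-associated steatohepatitis that joins a Western diet and sugar water with low-dose carbon tetrachloride, a liver toxin. After filtering and doublet removal, 69173 cells were kept, with 16363 in chow and 14001 in MASH at 12 weeks, and 21333 in chow and 17476 in MASH at 24 weeks. They carried 43461141, 56230427, 58631974 and 83707604 UMIs, in that order. MASH cells were deeper, with medians of 2974 and 3166 UMIs against 1980 and 2065 in chow. No group had a replicate library. The 95% intervals given with ratios, CPM values and shares cover counting error only, and a difference beyond its interval is one between these libraries, not yet between the diets.

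The first comparison asked how the cell makeup differed between MASH and chow. Macrophages, monocytes, conventional dendritic cells, bile duct cells and stellate cells or fibroblasts took larger shares of the MASH libraries at both weeks, and hepatocytes smaller ones. Cluster 11, macrophage-like cells led by the complement genes C1qa, C1qb and C1qc, held 0.953% of chow and 4.68% of MASH cells at 12 weeks (ratio 4.91, 4.11 to 5.88), and 0.281% and 6.97% at 24 weeks (24.8, 19.1 to 32.7). The later ratio was 55.8 under a stricter cell filter and 37.5 against chow cells with hashtags 5 to 8. Monocyte-like cells went from 1.95% to 3.76% (1.93, 1.67 to 2.22) and from 1.71% to 6.09% (3.57, 3.17 to 4.03), or 5.48 at 24 weeks with no doublet removal and 2.91 and 6.57 at resolution 0.5. Conventional dendritic-like cells, the main antigen-presenting cells, were 2.04 times (1.75 to 2.38) and 2.43 times (2.16 to 2.74) as frequent in MASH.

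Cholangiocyte-like cells, which line the bile ducts, were 2.66 times (1.99 to 3.58) as frequent at 12 weeks and 14.9 times (10.96 to 20.6) at 24 weeks, from 45 chow cells. The later ratio was 9.85 with no doublet removal and 110 against chow cells with hashtags 5 to 8. The ratios for stellate-like cells, which may include fibroblasts, were 2.59 (2.02 to 3.34) and 6.44 (4.06 to 10.7), from only 22 such cells in 24-week chow. Clec3b, among the leading genes of this group, itself differed between the diets. Their later ratio ranged from 3.58 with no doublet removal to 46.4 against hashtags 5 to 8. Hepatocyte-like cells, largely removed by the gradient, made up 8.29% and 9.15% of chow against 2.99% and 3.50% of MASH cells, with ratios of 0.360 (0.322 to 0.402) and 0.382 (0.349 to 0.419). T-cell-like cells had ratios of 0.905 (0.861 to 0.951) and 0.886 (0.849 to 0.925). The B-cell-like share had a ratio of 1.00 (0.959 to 1.05) at 12 weeks and 0.805 (0.777 to 0.835) at 24 weeks. For NK-like cells the ratios were 1.27 (1.17 to 1.37) and 1.09 (1.004 to 1.18), for endothelial-like cells 0.861 (0.798 to 0.929) and 0.802 (0.707 to 0.910), and for plasma-like cells 0.661 (0.514 to 0.845) and 0.820 (0.650 to 1.03). Against chow cells with hashtags 1 to 4 the 24-week ratios of these 3 classes turned to 0.846, 1.09 and 1.22, and that of endothelial-like cells was 1.01 with no doublet removal. Erythroid-like cells had ratios of 1.24 and 3.16, plasmacytoid dendritic-like cells 1.51 and 0.968, and basophil- or mast-like cells 1.38 and 0.922. In alternatives the 24-week plasmacytoid ratio was up to 1.22 and the basophil- or mast-like ratios went to 0.940 and 1.51.

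Neutrophil-like cells were 1.97 times (1.60 to 2.43) as frequent in MASH at 12 weeks and 1.20 times (1.11 to 1.29) at 24 weeks. The later ratio depended on part of the chow library: it was 4.804 against the chow cells with hashtags 1 to 4 and 0.590 against those with hashtags 5 to 8. The 24-week hepatocyte-like ratio was 0.639 against hashtags 1 to 4 and 1.70 against hashtags 5 to 8, a split that leaves out chow cells without a hashtag, and 57.7% of hepatocyte-like cells had none.

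**Figure D1:**
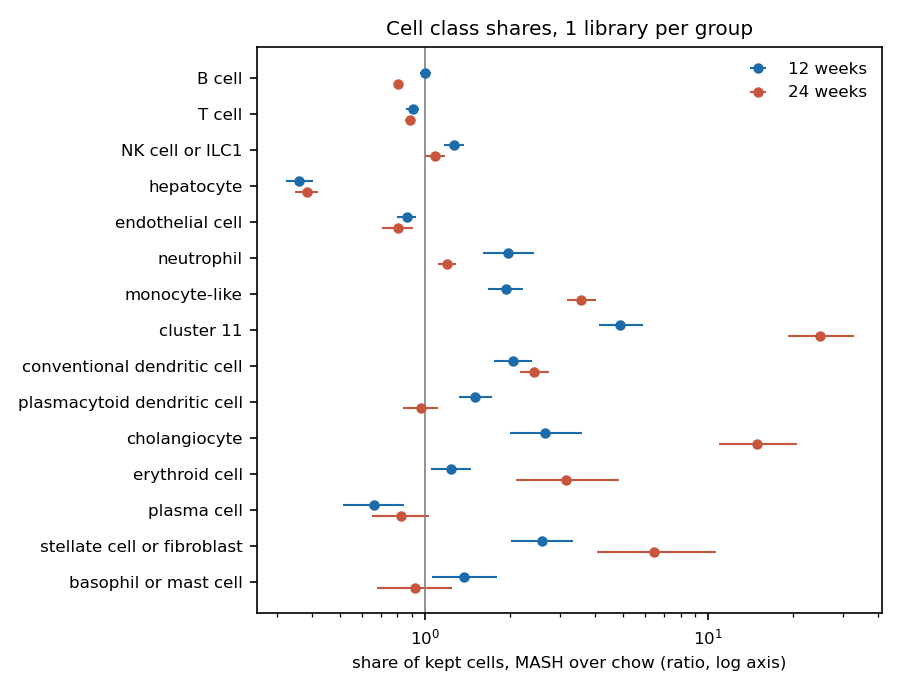
Share of kept cells in each class in MASH divided by that in chow, on a log axis, with 1 point per class and week and bars for the 95% counting interval. Cluster 11 lies at 4.91 and 24.8 and hepatocyte-like cells at 0.360 and 0.382.

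The series was made to look at uPAR, the receptor of the plasminogen activator urokinase, encoded by Plaur (ENSMUSG00000046223, a protein-coding gene on the plus strand of chromosome 7 from 24462484 to 24475968 in GRCm38). Over all kept cells Plaur was 94.4 CPM in both libraries at 12 weeks (ratio 1.00, 0.959 to 1.04), and 77.7 CPM in chow against 77.9 in MASH at 24 weeks (1.00, 0.965 to 1.04). The ratio was 0.866 at 12 weeks without neutrophil-like, hepatocyte-like, erythroid-like, mixed and unnamed cells. At 24 weeks it was 1.14 or 0.841 against hashtags 1 to 4 or 5 to 8 of chow. Within monocyte-like, B-cell-like, plasmacytoid dendritic-like and cholangiocyte-like cells Plaur was lower in MASH at both weeks, beyond the counting interval. Across single hashtags, the chow and MASH ranges stayed apart in monocyte-like cells but overlapped in B-cell-like and plasmacytoid dendritic-like cells. Cholangiocyte-like cells of chow had no hashtag values. In monocyte-like cells Plaur was 430 CPM in chow and 266 in MASH at 12 weeks (0.618, 0.556 to 0.687), and 319 and 196 at 24 weeks (0.614, 0.558 to 0.677). Neutrophil-like cells had the highest level, 631 against 596 CPM (0.946, 0.780 to 1.15) and 520 against 419 (0.806, 0.749 to 0.869).

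B-cell-like cells had 267 CPM in chow and 205 in MASH (0.769, 0.721 to 0.820) at 12 weeks, and 91.9 and 78.8 at 24 weeks (0.857, 0.792 to 0.928). Plasmacytoid dendritic-like cells had ratios of 0.808 (0.712 to 0.917) and 0.740 (0.653 to 0.838), conventional dendritic-like cells 0.898 (0.716 to 1.13) and 0.799 (0.630 to 1.02; 1.099 against hashtags 5 to 8), and plasma-like cells 0.611 (0.456 to 0.814) and 1.26 (0.830 to 1.91; 0.462 in single-hashtag cells). Cholangiocyte-like cells had 0.374 (0.234 to 0.602) and 0.244 (0.192 to 0.3125). The latter rests on 45 chow cells, at a median depth of 20822 UMIs against 10030.5 in MASH. Every stress-list gene except Hsp90aa1 was also lower in these MASH cells at 24 weeks. In cluster 11 the ratio was 1.19 (0.899 to 1.62) at 12 weeks and 0.528 (0.386 to 0.740) at 24 weeks, where a stricter cell filter gave 1.13. Endothelial-like cells showed 1.13 and 0.992, the latter 1.90 against hashtags 5 to 8, and the T-cell-like level was between 2.02 and 8.57 CPM in all libraries. The classes that supplied the Plaur UMIs differed. At 12 weeks B-cell-like cells gave the largest part, 45.2% in chow and 35.1% in MASH. Cluster 11 and monocyte-like cells gave 1.29% and 14.3% in 12-week chow and 9.76% and 16.7% in MASH. At 24 weeks the monocyte-like part was 12.6% in chow and 24.1% in MASH, cluster 11 gave 15.3% in MASH, and the B-cell-like part was 32.2% in chow and 17.1% in MASH.

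The share of cells with at least 1 Plaur UMI was 15.7% in chow and 20.3% in MASH at 12 weeks, and 12.8% and 18.6% at 24 weeks. With every cell thinned to 1000 UMIs the shares were 9.22% (8.74 to 9.71), 8.54% (8.06 to 9.05), 6.88% (6.53 to 7.26) and 7.05% (6.66 to 7.45), after leaving out 2725, 1396, 2578 and 962 shallower cells, so at equal depth the intervals of chow and MASH overlapped at both weeks. T-cell-like cells, taken here as the background level, had a UMI in 2.31%, 2.44%, 0.594% and 0.928% of cells at median depths of 2621, 3469, 2712 and 3337 UMIs, and thinned in 0.862%, 0.657%, 0.224% and 0.281%. Among monocyte-like cells, at median depths of 4195, 6212, 4626 and 6897 UMIs, the shares were 78.1%, 67.9%, 65.1% and 60.5%, and thinned 35.7%, 22.5%, 25.8% and 17.3%, with 0, 2, 3 and 5 cells too shallow. Neutrophil-like cells had 52.0%, 55.3%, 45.5% and 47.0%, and thinned 48.2%, 40.0%, 36.3% and 30.6%, with 65, 43, 341 and 192 cells too shallow.

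**Figure D2:**
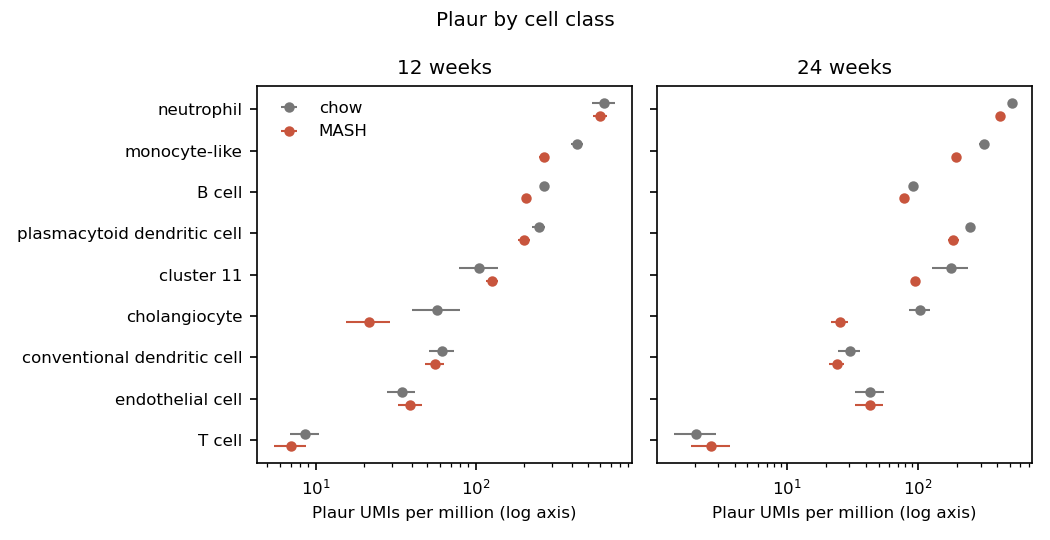
Plaur in CPM on a log axis for 9 cell classes at 12 and 24 weeks, 1 point per library with bars for the 95% Poisson interval, chow in grey and MASH in red. Monocyte-like cells lie at 430 and 319 CPM in chow and at 266 and 196 CPM in MASH.

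The uPAR and plasminogen activation list, which holds Plaur with its ligand and inhibitors, was read in the macrophage lineage. In monocyte-like cells its median log2 ratio was −0.01 at 12 weeks (1 of 5 members at least 2-fold higher, 0 lower and 4 between) and 0.20 at 24 weeks (1 higher, 0 lower and 5 between). Serpinb2, an inhibitor of urokinase, was 0.554 times chow (0.419 to 0.736) and 0.665 times (0.506 to 0.882). In cluster 11 the list median was 1.16 (0.49 to 1.69) and 0.22 (−0.50 to 0.90), but 0.87 and −0.34 with the members at 0 chow UMIs set to their bounds, with Lrp1, which clears urokinase complexes, at 2.25 and 1.55 times chow and Plau, urokinase itself, at 1.83 (0.859 to 4.67) and 1.01. With no doublet removal the 12-week monocyte-like median became 0.61 and the 12-week Serpinb2 ratio 1.54, and a stricter cell filter moved the 24-week median of cluster 11 to −0.59.

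Monocyte-like cells of MASH held more transcripts of osteopontin, the secreted protein encoded by Spp1, while most genes of antigen presentation stayed between the 2-fold limits. At 12 weeks the Spp1 level in these MASH cells was below 10% of that in cluster 11. Spp1 is therefore open to RNA of other cells here. The MHC class II list had a median log2 ratio of 0.41 (0.32 to 0.59) at 12 weeks, with all 10 members between (0.22 in single-hashtag cells, 0.25 with no doublet removal and 0.0708 at resolution 0.5), and 0.85 (0.69 to 0.97) at 24 weeks, with 3 higher and 7 between. H2-Ab1 was 1.55 times (1.42 to 1.70) and 2.20 times chow (2.07 to 2.33), and H2-Eb1 1.53 and 2.65 times. The lipid- and scar-associated list had medians of 0.48 (0.14 to 0.55; 6 higher, 0 lower, 11 between) and 0.46 (0.38 to 0.65; 5 higher, 0 lower, 12 between). Spp1 was 8.04 times (2.62 to 40.1, on 3 chow UMIs) and 23.4 times chow (10.7 to 63.9), while the lipid receptor gene Trem2 was at 0.851 (0.697 to 1.04) and 1.65 (1.33 to 2.06).

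Among inflammatory cytokines and chemokines the medians were 0.48 (4 higher, 0 lower, 12 between) and 0.18 (2 higher, 0 lower, 14 between). Cxcl16, a chemokine for Cxcr6-bearing lymphocytes, was 3.84 times (2.54 to 6.06) and 2.30 times chow (1.71 to 3.14), and Il1b was at 0.945 and 1.26. The cholesterol list had medians of −0.07 (3 higher, 2 lower, 6 between) and −0.26 (1 higher, 2 lower, 8 between), and its members parted. The sterol sensor Nr1h3 was 4.24 times (2.28 to 8.73) and 3.08 times chow (1.94 to 5.20) and the efflux pump Abca1 3.56 and 1.68 times, whereas Hmgcs1, of cholesterol synthesis, was at 0.529 and 0.478. The senescence list had medians of 0.01 (0.03 with Cxcl1 at its bound; 2 higher, 1 lower, 10 between) and −0.07 (3 higher, 1 lower, 9 between), with the cell cycle inhibitor Cdkn1a at 0.909 and 0.956. The stress list, a sign of handling of the tissue, was at 0.18 (0.12 to 0.27) and −0.15 (−0.17 to −0.11), and its 12-week median turned to −0.0937 with no doublet removal and −0.25 at resolution 0.5.

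In these cells 8 genes were at least 2-fold higher and 8 at least 2-fold lower in MASH at both weeks, of 5388 that could be compared, where independent lists would share 0.368 and 0.125. The counts were 36 and 15 under a stricter cell filter, 17 and 3 in single-hashtag cells, 96 and 31 with no doublet removal and 22 and 1 against hashtags 5 to 8, and 6 of the 8 and 8 are open to RNA of other cells, with a level below 10% of that in another class. Those named by size were Axl, a receptor for dying cells, at 3.80 and 2.93 times chow, the Fc receptor gene Fcgr1 at 2.35 and 2.49, and the chemotactic receptor gene Gpr183 at 2.15 and 2.24. On the lower side were Mdm1 at 0.301 and 0.345, Scnn1a at 0.432 and 0.413, and Rfx2 at 0.481 and 0.441. With no doublet removal or at resolution 0.5, where cells of cluster 11 joined this class, the lipid- and scar-associated medians were 2.07 and 2.40 or 2.09 and 2.43.

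Cluster 11 was the group in which the lipid- and scar-associated list stood highest in MASH. Its median log2 ratio was 1.99 (1.80 to 2.25) at 12 weeks, with 16 of 18 members at least 2-fold higher, 0 lower and 2 between, and 1.70 (1.55 to 1.84) at 24 weeks, with 15 higher, 0 lower and 3 between (1.71 with Atp6v0d2, at 0 chow UMIs, at its bound). Both medians lay at the percentile of 100 among matched random lists. Gpnmb (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), a lysosomal membrane glycoprotein, was 15.4 times (10.4 to 23.8) and 14.3 times chow (7.79 to 29.9). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) was 3.86 times (3.08 to 4.91) and 10.8 times chow, and Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) 108 times (36.8 to 522, on 3 chow UMIs) and 12.5 times. Cathepsin D (Ctsd) was at 7.36 and 3.32 (the latter 1.00 under a stricter cell filter), the fatty acid carrier Fabp5 at 6.63 and 2.02, the tetraspanin gene Cd9 at 2.29 and 3.79, and Itgax at 0.781 and 1.12. Gpnmb, Trem2, Lpl and Mmp12 of this list are among the 10 leading genes of the cluster, though list genes were not used for clustering. Leading genes were ranked over all libraries together, and most cells of the cluster came from MASH, so this is no separate support.

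The interferon response list was lower in MASH cells of cluster 11, with medians of −0.70 (−1.09 to −0.32; 0 higher, 5 lower, 6 between) and −1.69 (−1.80 to −1.16; 0 higher, 6 lower, 5 between). They turned to 0.16 and 1.01 under a stricter cell filter, which matched 880 cells of the cluster, and the 24-week one was −0.0695 against chow hashtags 5 to 8. Cxcl9, a chemokine induced by interferon gamma, was 0.0664 times chow (0.0543 to 0.0811) and 0.114 times, and the guanylate-binding protein gene Gbp2 0.166 and 0.136 times. The oxidative stress list had medians of 1.18 (6 higher, 0 lower, 4 between) and 0.42 (0 higher, 0 lower, 9 between, 1 undecided), with haem oxygenase (Hmox1) at 2.37 and 1.21. MHC class II stood at −0.86 (1 higher, 1 lower, 8 between) at 12 weeks and 0.45 (0 higher, 1 lower, 8 between, 1 undecided) at 24 weeks, with H2-Aa at 0.562 and 1.56. With members at 0 chow UMIs at their bounds, the oxidative stress medians were 1.19 and 0.35 and the 24-week MHC class II median 0.24. The senescence list was at −0.08 (6 higher, 1 lower, 7 between) and −0.07 (4 higher, 1 lower, 7 between, 2 undecided; −0.0051 at the bounds), and Cdkn1a at 0.608 and 0.449. Beside these lists, the stress list was at −0.75 (−0.82 to −0.66; 0 higher, 3 lower, 11 between) and −0.33 (−0.41 to −0.25; 0 higher, 1 lower, 13 between), the latter 0.30 under the stricter filter.

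By size alone, ranked after the data were seen, Arg1 (arginase) was 22.3 times (11.7 to 48.8) and 49.4 times chow (8.86 to 1953, on 1 chow UMI), and Ltc4s, of leukotriene synthesis, 16.5 times (9.98 to 29.5; 1.62 under a stricter cell filter) and at least 2.38-fold higher. Ctsk, another cathepsin, was at least 11.4-fold and at least 3.46-fold higher, with 0 chow UMIs. On the lower side were the chemokine gene Ccl24 at 0.195 and 0.0895, Ly6i at 0.104 and 0.271, and Plac8 at 0.284 and 0.204, though the 24-week Plac8 ratio turned to 4.91 under the stricter filter and to 1.64 against hashtags 5 to 8. Chow cells of cluster 11 numbered 156 and 60, at median depths of 2083 and 3044 UMIs against 4531 and 6533 in MASH. In cells of 2000 to 5000 UMIs alone the list medians were 1.32 (1.17 to 1.60) and 0.47 (0.10 to 0.80). At 24 weeks 7 general macrophage genes, C1qa, C1qb and C1qc among them, had a median of 1.66 (1.29 to 1.77), about that of the list itself, against 0.44 (0.29 to 0.53) at 12 weeks. A stricter cell filter turned the 24-week MHC class II median to −0.08, and against hashtags 5 to 8 it was −0.27.

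**Figure D3:**
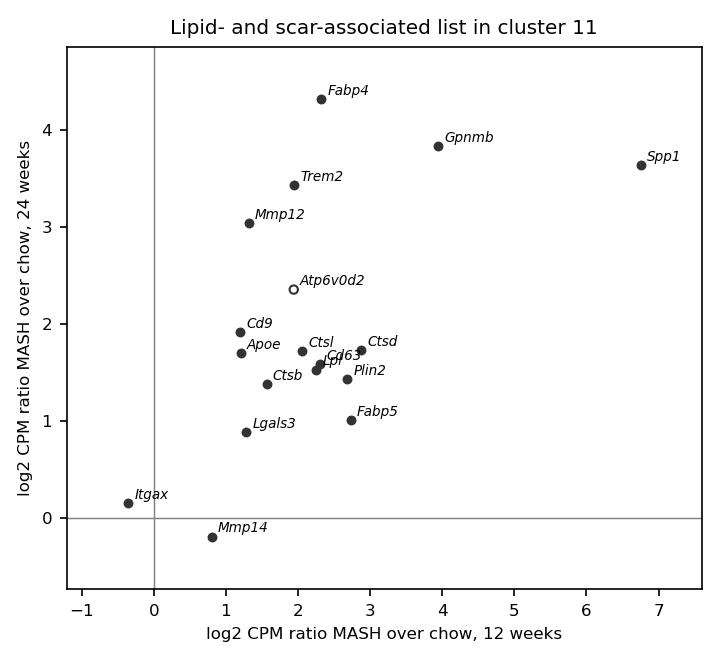
Log2 CPM ratio of MASH over chow in cluster 11 at 12 weeks (horizontal axis) and 24 weeks (vertical axis), 1 point per gene of the lipid- and scar-associated list. Spp1 lies farthest right, on 3 chow UMIs at 12 weeks, and the open point, Atp6v0d2, is drawn at its lower bound on the vertical axis because chow had 0 UMIs at 24 weeks.

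T-cell-like cells of MASH carried more transcripts of the inhibitory receptor genes Pdcd1, Lag3 and Tigit and of granzyme K, and fewer of interleukin 4. The activation, residency and exhaustion list had a median log2 ratio of 0.53 (0.45 to 0.63) at 12 weeks, with 7 members at least 2-fold higher, 1 lower and 8 between, and 1.16 (0.99 to 1.33) at 24 weeks, with 8 higher, 0 lower and 8 between. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), encoding the inhibitory receptor PD-1, was 3.30 times (2.34 to 4.76) and 7.32 times chow (5.87 to 9.22). Other inhibitory receptor genes were Lag3 at 3.95 (2.71 to 5.89) and 4.64 (3.56 to 6.11) and Tigit at 2.07 and 4.96, and the exhaustion regulator Tox was at 2.18 and 2.52. Cxcr6, of tissue residency, was at 0.494 and 0.818, and Ifng at 0.849 and 0.563.

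Different clusters held most of the class in the diets, and these values stand beside that shift. Cluster 2, led by Il4 and Trbv13-2, held 62.2% and 58.6% of T-cell-like cells in chow but 26.9% and 17.1% in MASH. Cluster 3, led by Cd8b1 and Cd8a with Gzmk among its leading genes, held 15.5% and 22.2% in chow against 48.5% and 41.6% in MASH. Cluster 10, with Foxp3 and Ctla4, held 5.42% and 7.51% against 13.8% and 32.2%. Il4, Gzmk and Ctla4 are leading genes of these clusters, and stood at 0.408 and 0.159, 9.72 and 4.64, and 1.45 and 3.33 times chow. Gzmk and Ctla4 belong to the activation list, whose genes were not used for clustering. Within cluster 3 alone Gzmk was 6.22 times (4.20 to 9.63) and 3.02 times chow (2.61 to 3.51). In cluster 2 it was 4.27 and 5.36 times chow, and in cluster 10 it was 4.49 times at 24 weeks. Cluster 28 had 8.41 times at 12 weeks but 0.985 (0.716 to 1.35) at 24 weeks. The intervals in cluster 18 included no difference at both weeks.

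The naive and central memory list had medians of 0.32 (0.17 to 0.38; 0 higher, 0 lower, 7 between) and 0.38 (0.31 to 0.43; 0 higher, 0 lower, 7 between), with Tcf7, a transcription factor of memory T cells, at 1.39 and 1.30 but Satb1 at 0.765 and 0.572. The cell cycle list had medians of −0.56 (−0.69 to −0.43) and 0.28 (0.15 to 0.33), with all 12 members between the limits at both weeks, and the stress list 0.28 (2 higher, 0 lower, 12 between) and 0.12 (0 higher, 0 lower, 14 between). By the 2-fold rule 19 genes were higher and 18 lower at both weeks, of 5540, where independent lists would share 0.296 and 0.329, and 14 of these genes are open to RNA of other cells. With totals that leave out mitochondrial, ribosomal, haemoglobin and immunoglobulin genes 32 were higher, and against hashtags 5 to 8 of chow 29. Against hashtags 1 to 4 of chow 10 were lower. The counted genes included the granzyme gene Gzmm at 4.70 and 3.47 and Cd163l1, a marker of some gamma-delta T cells, at 2.61 and 3.85. Klra7, one of a family of near-identical receptor genes and so uncertain, was at 4.01 and 4.79. Lower were Zbtb16, the transcription factor of innate-like T cells, at 0.241 (0.204 to 0.283) and 0.245 (0.205 to 0.292; 0.501 against hashtags 1 to 4), Aqp9 at 0.322 and 0.265, F2rl2 at 0.323 and 0.330 and Dtx1, a Notch target, at 0.398 and 0.185. Against the 24-week chow cells of hashtags 1 to 4 the 24-week cell cycle median turned to −0.14, and the activation median was 0.82 against hashtags 1 to 4 and 1.75 against hashtags 5 to 8.

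**Figure D4:**
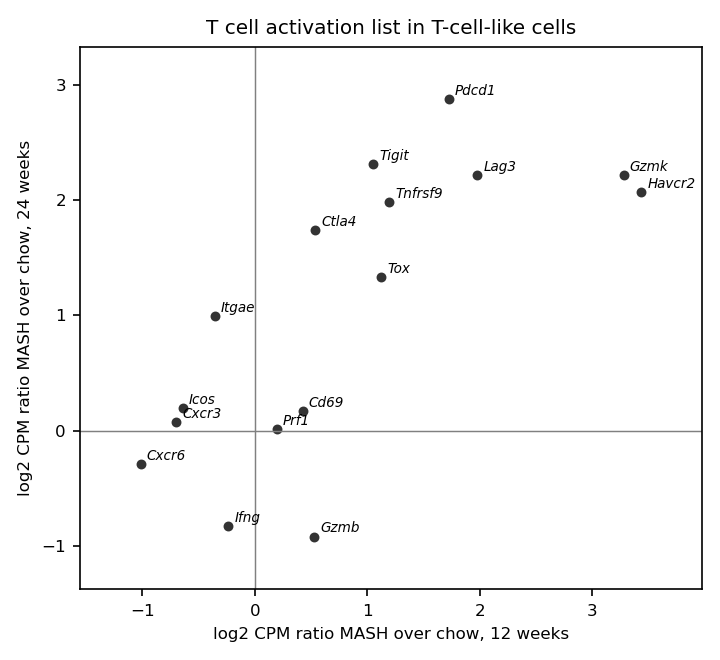
Log2 CPM ratio of MASH over chow in T-cell-like cells at 12 weeks (horizontal axis) and 24 weeks (vertical axis), 1 point per gene of the activation, residency and exhaustion list. Pdcd1 lies highest, at 7.32 times chow at 24 weeks, and Cxcr6 farthest left, at 0.494 times chow at 12 weeks.

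NK-like and B-cell-like cells had few genes past the 2-fold rule. In NK-like cells 7 genes were higher and 12 lower at both weeks, of 5786, where independent lists would share 0.118 and 0.310, and 10 are open to RNA of other cells. Only 6 were lower at a minimum of 100 UMIs and 5 against hashtags 5 to 8, where the 24-week Ada ratio given below was 0.848. The growth factor receptor gene Kit was 2.36 times (1.71 to 3.32) and 4.25 times chow (3.39 to 5.38), Cdk6 2.52 and 2.33, and Emb 2.19 and 2.34 times. Lower were Dtx1 at 0.326 and 0.125, Atp8a2 at 0.386 and 0.200, adenosine deaminase (Ada) at 0.308 and 0.466, and Rab11fip4 at 0.495 and 0.263. Cluster 8, led by Gzmc with Ncr1 and Xcl1, held 41.4% of the class in chow at both weeks against 45.5% and 78.6% in MASH, and cluster 9, led by Klra8, held the rest. In B-cell-like cells 2 genes were higher and 5 lower, of 5334, where independent lists would share 0.0247 and 0.0422, and 5 of these genes are open to RNA of other cells. The count was 8 lower at resolution 0.5. Il9r, the interleukin 9 receptor gene (ENSMUSG00000020279, chromosome 11, 32187541 to 32200279), was 4.67 times (3.54 to 6.26) and 3.50 times chow (3.03 to 4.07), and Fam129c was at 0.452 (0.381 to 0.535) and 0.398 (0.358 to 0.443). Fam129c leads cluster 12, which held 12.6% and 13.3% of B-cell-like cells in chow and 4.10% and 5.84% in MASH, and cluster 1, led by Cr2, held 33.5% and 30.6% against 68.3% and 56.3%.

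Endothelial-like cells of MASH held more interferon-induced transcripts by the list median, though at 12 weeks most members stayed between the 2-fold limits. Single genes of capillary endothelium, Cd34, Ednrb and Ly6c1, were higher too, but the capillarisation list as a whole was not more than 2-fold from chow. Ednrb, the endothelin receptor B gene (ENSMUSG00000022122, chromosome 14, 103814625 to 103844402), was 8.56 times (7.23 to 10.2) and 16.0 times chow (12.6 to 20.6), Ly6c1 3.94 and 10.5 times, and Igfbp3 5.40 and 3.98 times. The interferon response list had medians of 0.84 (0.55 to 0.99; 2 higher, 0 lower, 9 between) and 1.18 (0.90 to 1.41; 7 higher, 0 lower, 4 between), with the interferon regulator Irf7 at 2.48 and 3.21. Cxcl10 of the same list was at 2.10 and 0.544, the latter 1.30 against hashtags 1 to 4. The capillarisation list had medians of 0.18 (4 higher, 1 lower, 7 between) and 0.35 (4 higher, 2 lower, 6 between). They turned to −0.51 and −0.10 with no doublet removal, and the 12-week one to −0.0113 with cells weighted equally. Cd34 (ENSMUSG00000016494, chromosome 1, 194938819 to 194961279) was 2.29 times (1.75 to 3.03) and 5.47 times chow (4.04 to 7.54) and Sparcl1 7.99 (3.19 to 25.7) and 35.1 times (13.4 to 130), but the adhesion molecule gene Vcam1 was at 0.716 and 0.180.

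The sinusoidal identity list was at 0.06 (1 higher, 0 lower, 11 between) and −0.31 (1 higher, 0 lower, 11 between), with the fatty acid transporter gene Cd36 at 3.55 and 2.74. The stress list was at −0.12 (1 higher, 0 lower, 13 between) and −0.33 (0 higher, 2 lower, 12 between). By the 2-fold rule 27 genes were higher and 25 lower at both weeks, of 6906, where independent lists would share 0.812 and 1.38, and 16 are open to RNA of other cells. The counts were 17 and 7 at a minimum of 100 UMIs, 70 higher with no doublet removal, and 6 or 12 lower against hashtags 1 to 4 or 5 to 8. The 27 and 25 included Cfap69 at 58.7 (10.2 to 2350, on 1 chow UMI) and 14.1 (4.52 to 70.7, on 3 chow UMIs) and Obsl1 at 4.75 and 4.18. Lower were the neurotrophin gene Ntf3 at 0.154 and 0.117, Phlda1 at 0.286 and 0.280, angiogenin (Ang) at 0.351 and 0.344, and Dkk3 at 0.352 and 0.200. Cytl1 was at 0.159 at 12 weeks and at least 38.1-fold lower at 24 weeks. The 12-week sinusoidal median turned to −0.34 with no doublet removal.

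Stellate-like cells of MASH, ranked after the data were seen, held more Timp1, the inhibitor of matrix-degrading enzymes, and more Saa3, from 93 and 22 cells in chow and 206 and 116 in MASH. The matrix and activation list had medians of 0.38 (0.31 to 0.61; 5 higher, 3 lower, 9 between) and 0.60 (0.46 to 1.39; 7 higher, 0 lower, 9 between, 1 undecided), or 0.39 and 0.65 with members at 0 chow UMIs at their bounds. The 12-week median was 0.0451 with no doublet removal and 0.0842 with cells weighted equally. Timp1 (ENSMUSG00000001131, chromosome X, 20870166 to 20874735) was 12.9 times (9.39 to 18.3) and 12.7 times chow (6.40 to 29.4), fibronectin (Fn1) 3.16 and 4.09 times, and smooth muscle actin (Acta2) 2.24 and 3.91 times. Col1a1 was at 1.63 and 0.740 and Col3a1 at 1.25 and 0.727, but at 3.07 and 1.34 at 24 weeks against hashtags 1 to 4 of chow. Col4a1 was at 1.35 and 3.88 and Col6a1 at 1.24 and 2.15. Saa3, an acute-phase protein gene, was at least 476-fold and at least 657-fold higher, and the neutrophil chemokine gene Cxcl5 42.2 times chow (7.49 to 1672, on 1 chow UMI) and at least 12.5-fold higher. Ly6a was at 0.325 and 0.166 and gelsolin (Gsn) at 0.197 and 0.118. Gsn at 24 weeks was 1.27 in single-hashtag cells and 2.03 against hashtags 1 to 4 of chow, and the 24-week list median was −0.0097 against hashtags 5 to 8.

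Hepatocyte-like cells showed the most genes past the 2-fold rule among the 6 largest classes, 70 higher and 44 lower at both weeks of 3977, where independent lists would share 8.55 and 3.73, and 17 are open to RNA of other cells. The counts were 31 and 23 at a minimum of 100 UMIs, and 19 were lower against hashtags 5 to 8. Apoa4, an apolipoprotein of lipid transport, was 85.9 times (22.9 to 723, on 2 chow UMIs) and 35.0 times chow (17.3 to 82.6). The aldehyde dehydrogenase gene Aldh3a2 was at 6.92 (5.49 to 8.78) and 13.5 (10.8 to 17.0), Gulo, of vitamin C synthesis, at 10.3 and 5.64, Lect2 at 10.5 and 7.52, and Spp2 at 5.18 and 4.64. Lower were Etnppl, of phosphoethanolamine breakdown, at 0.106 and 0.207, Enho at 0.0210 (on 1 MASH UMI) and 0.258, and Whamm at 0.237 and 0.262. Serpina1e at 0.0250 and 0.0162 and Mup21 at 0.107 and 0.0861 belong to families of near-identical genes and are uncertain. The median depth of this class was 829 to 1407 UMIs, below that of the libraries, and against hashtags 5 to 8 of chow the 24-week Spp2 ratio was 1.22. Some genes varied widely between hashtags of 12-week MASH. Vtn, at 5.36 times chow, ran from 39.6 to 1371 CPM there, against 46.1 to 75.6 in chow. Others varied less, such as Pcna at 26.9 to 47.3 CPM in MASH. Hashtag ranges of the genes named above are not given here.

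Neutrophil-like cells of MASH held more cell cycle transcripts, which held only after doublet removal, and more Fcnb. The cell cycle list had medians of 1.17 (0.54 to 1.57; 5 higher, 0 lower, 5 between, 1 undecided) and 1.85 (10 higher, 0 lower, 2 between). With Tyms, at 0 chow UMIs, at its bound the 12-week median was 0.99. Cluster 25, led by the granule genes Camp, Ngp and Ltf, held 24.0% and 6.46% of the class in chow against 18.6% and 18.8% in MASH. Fcnb, a ficolin gene, was 5.60 times (3.20 to 10.7) and 7.47 times chow (5.28 to 10.9), the lectin gene Clec4n 4.52 and 8.66 times, Marcksl1 2.66 and 3.28 times, and Pclaf, of DNA replication, 2.97 and 8.86 times. Ncam1 was at least 3.87-fold higher at 12 weeks and 2.83 times chow at 24 weeks. The adhesion molecule gene Jaml was lower, at 0.483 (0.328 to 0.716) and 0.323 (0.294 to 0.354). The rule counted 17 genes higher and 6 lower at both weeks, of 1952, where independent lists would share 5.16 and 0.314, and 5 are open to RNA of other cells. At a minimum of 100 UMIs 4 were higher and 0 lower. Beside these, the stress list was at 0.31 (2 higher, 0 lower, 12 between) and −0.67 (0 higher, 1 lower, 13 between), with Fosb at 0.715 and 0.415. With no doublet removal the cell cycle medians turned to −1.18 and −0.49 and Pclaf to 0.117 and 0.231, the 24-week Fcnb ratio was 1.44, and with cells weighted equally the 12-week median was −0.38.

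Conventional dendritic-like cells of MASH held more interleukin 12 p40 (Il12b). The interferon response list had a higher median, though most of its members stayed between the 2-fold limits. Il12b was 10.3 times (6.59 to 17.1) and 11.5 times chow (6.37 to 23.4) and Zmynd15 5.24 times at both weeks. Both help to define cluster 29, which held 7.84% and 2.66% of this class in chow and 21.4% and 10.8% in MASH. The interferon response list had medians of 0.32 (0.05 to 0.88; 4 higher, 1 lower, 6 between) and 0.84 (0.64 to 0.95; 3 higher, 0 lower, 8 between), with the antiviral gene Rsad2 at 2.85 and 2.48 and Oas1a, outside the list, at 4.85 and 3.22. The lipid- and scar-associated list was at 0.32 (0.05 to 0.61; 4 higher, 0 lower, 11 between) and 0.86 (0.63 to 1.26; 8 higher, 0 lower, 9 between; 0.89 with Gpnmb at its bound), with Cd63 at 2.47 and 3.22 and Apoe at 1.81 and 2.97. The lectin gene Mgl2 was at 3.52 and 4.15 and H2-Eb2 at 3.42 and 4.75, and lower were Rgcc at 0.450 and 0.415 and Ripor2 at 0.489 and 0.492. The rule counted 28 genes higher and 9 lower at both weeks, of 5485, where independent lists would share 1.03 and 0.173, and 12 are open to RNA of other cells. Only 3 were lower at a minimum of 100 UMIs. The 24-week interferon median was 0.30 against hashtags 1 to 4 of chow and 1.49 against hashtags 5 to 8.

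The last comparison set 24 against 12 weeks within each diet, with 1 library per week. Neutrophil-like cells were more frequent at 24 weeks, by 7.45 times (6.29 to 8.87) in chow and 4.53 times (3.96 to 5.19) in MASH, and endothelial-like cells less, at 0.299 and 0.279 times. Cluster 11 went to 0.295 times (0.215 to 0.400) its 12-week share in chow and 1.49 times (1.35 to 1.64) in MASH, stellate-like cells to 0.181 and 0.451 times, erythroid-like cells to 0.0909 and 0.232 times and B-cell-like cells to 1.51 and 1.21 times. Plaur over all cells was lower at 24 weeks, at 0.823 (0.789 to 0.858) in chow and 0.825 (0.796 to 0.856) in MASH. In B-cell-like cells it was 0.345 (0.322 to 0.369) and 0.385 (0.357 to 0.414) times its 12-week level, in conventional dendritic-like cells 0.487 and 0.433, in monocyte-like cells 0.742 and 0.737, and in neutrophil-like cells 0.824 and 0.703. Most stress-list genes were higher at 24 weeks in B-cell-like cells. Hspa1a went from 33.4 to 2252 CPM in chow and from 86.1 to 1556 in MASH. Nr4a1 was lower in both diets and Hsp90aa1 was lower in MASH. Atf3 was nearly level, at 157 and 159 CPM in chow and 132.6 and 132.1 CPM in MASH. Handling and batch could therefore not be told apart from week. Within 24-week chow, cells of hashtags 1 to 4 had 1.22% to 2.08% neutrophil-like cells and those of hashtags 5 to 8 had 13.1% to 14.5%, so most of the higher share in chow lay in the latter.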

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

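The tests of cluster 11, of T-cell-like cluster 3 and of T-cell-like single-hashtag cells were chosen after the results were seen. Most results here stand out because the counting intervals of the 12- and 24-week differences lie on opposite sides of no difference. With 1 library per group the difference between the weeks was not tested in any of them.

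The share of unnamed cells in MASH was 1.17 times that in chow at 12 weeks and 0.761 times at 24 weeks. The cell cycle list in T-cell-like cells had median log2 ratios of −0.56 and 0.28. The sinusoidal identity list in endothelial-like cells had 0.064 and −0.31. The list of dissociation and storage stress had 0.31 and −0.67 in neutrophil-like cells and 0.18 and −0.15 in monocyte-like cells. MHC class II genes in cluster 11 had −0.86 and 0.45, or 0.24 at 24 weeks with 1 member at 0 chow UMIs set to its bound. In alternatives some of these fell on the same side at both weeks: with no doublet removal the 12-week sinusoidal median was −0.34 and the 12-week monocyte-like stress median −0.0937 (−0.25 at resolution 0.5), the 24-week T-cell-like median was −0.14 against hashtags 1 to 4, and the 24-week MHC class II median −0.08 under the stricter filter.

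The hashtag counts, whose meaning the labels do not give, showed signal outside the genes. Of the cells that passed the filters, 20.26% in chow and 26.67% in MASH at 12 weeks, and 22.82% and 23.91% at 24 weeks, had more than 1 hashtag above its threshold. No library without hashtags was there to set beside them.

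Plaur was lower in monocyte-like cells of MASH, at 0.618 and 0.614 times chow. RNA of other cells diluting the class would lower its own markers too. The median log2 ratio of 10 fixed monocyte markers was instead above 0, at 0.34 (0.27 to 0.43) and 0.22 (0.14 to 0.32). This argues against dilution only if the markers did not themselves rise in MASH. The markers also named the class and were not kept out of the genes for clustering, so dilution is not excluded. A shift between the clusters of the class is argued against, since within cluster 13 alone the Plaur ratio was 0.622 (0.555 to 0.697) and 0.611 (0.550 to 0.680). A difference between single libraries or batches and an effect of the diet both stay open, the latter untested.

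The lipid- and scar-associated list was higher in cluster 11 of MASH, with medians of 1.99 and 1.70. At 12 weeks the values argue against diluted chow cells, as 7 macrophage genes had a median of only 0.44 (0.29 to 0.53). They also argue against fewer UMIs per cell in chow as the full explanation, as cells of 2000 to 5000 UMIs gave 1.32 (1.17 to 1.60). That value lay below the 1.99 of all cells, so depth may account for part of the 12-week result. At 24 weeks both tests came out as these explanations predict, with 1.66 (1.29 to 1.77) for the macrophage genes and 0.47 (0.10 to 0.80) at matched depth. RNA of other cells or low depth in the 60 chow cells may therefore account for the 24-week result, of which 26 chow cells entered the matched comparison. At 12 weeks an effect of the diet stays open as untested, beside library and batch.

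The activation list was higher in T-cell-like cells of MASH, with medians of 0.53 and 1.16. With every cluster at its share in chow the medians were 0.41 (0.28 to 0.45) and 0.42 (0.30 to 0.52). The 12-week value passed the limit set beforehand against a shift between clusters, but its interval reached below that limit. The 24-week value fell between the limits set beforehand, yet far below 1.16, so the shift may carry a large part of that median. How far the shift explains the result was left undecided. A shift with no difference inside cluster 3 is argued against, since the medians within it were 0.39 (0.29 to 0.61) and 0.57 (0.32 to 0.72). Other clusters differed less at 12 weeks. Cluster 2 had 0.25 (0.01 to 0.42) and 0.19 (0.02 to 0.28), and cluster 28 had 0.33 and 0.27. Cluster 10 had 0.14 (−0.17 to 0.39) and 0.60, and cluster 18 had −0.21 (−0.63 to 0.23) and 0.60. Doublets are argued against at 24 weeks, as single-hashtag cells gave 1.07. The shift between clusters, library and batch, and an untested effect of the diet stay open.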

How the results depend on the processing

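The runs with single-hashtag cells, other denominators and chow hashtags 1 to 4 or 5 to 8 were chosen after the results were seen. So were the run without neutrophil-like, hepatocyte-like, erythroid-like, mixed and unnamed cells and all runs for the comparison of weeks. No paired analysis was possible because the groups compared share only the replicate number 1, which gives no block of more than 1 pair. Week could serve as a block of another kind, in a model of diet and week together, which was not fitted. Each alternative changed 1 step, with 3 limits moved together in the stricter filter and 2 in the lower gene minimum, and a value counts as kept when it stayed inside the counting interval of the reported one, or for gene counts within 1.5 times of it. Of all values, 2603 were kept, 833 moved and 39 changed direction. A change of direction was counted only where the reported value stood out. This meant a ratio whose interval excluded no difference, for genes also at least 2-fold, or a list median at an extreme percentile. Other values that crossed to the opposite side are among those kept or moved. Where a value moved or turned, the cause was not tested unless stated.

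Several results kept their direction in every alternative setting run for them, and the tests of explanations, which gave lower values, stand apart. Plaur in monocyte-like cells stayed between 0.505 and 0.642 times chow at 12 weeks and between 0.456 and 0.659 at 24 weeks. The T-cell-like activation median ranged from 0.52 to 0.70 and from 0.82 to 1.75, and with clusters at their chow shares it was 0.41 and 0.42. In cluster 11 the lipid- and scar-associated median ranged from 1.58 to 2.66 and from 1.46 to 2.25, and at matched depth it was 1.32 and 0.47. The endothelial-like interferon median ranged from 0.53 to 0.92 and from 0.71 to 1.23. With no doublet removal and at resolution 0.5 no cluster matched cluster 11, so these runs gave no value for it. The stricter filter matched it in only 880 cells.

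With no doublet removal, share ratios of MASH over chow moved to B-cell-like 0.935 at week 12 and 0.889 at week 24, T-cell-like 0.985 at week 24, NK-like 1.18 at week 24 and hepatocyte-like 0.321 at week 12 and 0.339 at week 24. They were also endothelial-like 1.01 at week 24, neutrophil-like 1.002 at week 24, monocyte-like 2.87 at week 12 and 5.48 at week 24, and conventional dendritic-like 2.66 at week 12. Further ones were cholangiocyte-like 3.84 at week 12 and 9.85 at week 24, erythroid-like 1.48 at week 12, and stellate-like 3.74 at week 12 and 3.58 at week 24. Cells with Plaur made up 17.3% and 23.0% of chow and MASH at 12 weeks, and 15.5% and 20.6% at 24 weeks. The neutrophil-like share in chow was 9.19 times as high at 24 as at 12 weeks. Plaur over all kept cells was 0.939 at week 12, in neutrophil-like cells 0.957 at week 24 and in monocyte-like cells 0.505 at week 12.

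The 2-fold rule then counted endothelial-like 70 higher, monocyte-like 96 higher and 31 lower, and plasmacytoid dendritic-like 8 higher and 6 lower genes. The T-cell-like cell cycle median was −0.11 at week 12 and 0.78 at week 24. Endothelial-like medians were interferon 0.73 at week 24, stress 0.0535 at week 12 and −0.0742 at week 24, and sinusoidal identity −0.34 at week 12 and −0.39 at week 24. Capillarisation turned to −0.51 at week 12 and −0.0993 at week 24. In neutrophil-like cells the cell cycle median turned to −1.18 at week 12 and −0.49 at week 24, and stress was −0.21 at week 24. Ncam1 there was 0.412 at week 24, Pclaf 0.117 and 0.231, Stmn1 0.484 at week 24, and Top2a 0.702 and 0.705. Monocyte-like medians were uPAR 0.61 at week 12, stress −0.0937 and −0.46, lipid and scar 2.07 and 2.40, cytokine 0.0873 and 0.37, and MHC class II 0.25 at week 12. Conventional dendritic-like medians were interferon 0.64 and lipid and scar 1.31 at week 24, and the stellate-like matrix median was 0.0451 at week 12.

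Under the stricter filter, shares gave T-cell-like 0.840 at week 24, hepatocyte-like 0.408 at week 12 and 0.468 at week 24, neutrophil-like 2.83 at week 12, and monocyte-like 4.4 at week 24. Cluster 11 came to 3.36 at week 12 and 55.8 at week 24, and plasma-like cells to 0.639 at week 24. Cells with Plaur were 17.3% and 21.5% at week 12 and 13.7% and 19.4% at week 24. From 12 to 24 weeks the neutrophil-like share in chow went to 9.91 times, and cluster 11 to 0.125 times in chow and 2.07 times in MASH. Plaur was 1.42 in hepatocyte-like cells at week 12 and turned to 1.13 in cluster 11 at week 24. The 2-fold rule counted T-cell-like 11 lower, neutrophil-like 2 lower, monocyte-like 36 higher and 15 lower, and cluster 11 4 lower genes. The neutrophil-like stress median was 0.59 at week 12. Monocyte-like medians were stress 0.0616 and −0.25, lipid and scar 1.04 and 1.11, and at week 24 cytokine −0.000137 and MHC class II 1.13. In cluster 11 they were uPAR −0.59 at week 24, interferon 0.16 and 1.01, stress −0.89 and 0.30, lipid and scar 2.66 and 1.53, MHC class II −0.27 and −0.0818, and oxidative stress 0.0203 at week 24. Cxcl10 turned to 1.15 at week 12, and Apoe to 0.918, Isg15 to 2.20 and Plac8 to 4.91 at week 24.

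At resolution 0.5, the monocyte-like share ratio was 2.91 at week 12 and 6.57 at week 24, and Plaur in these cells 0.551 and 0.456. Cells of cluster 11 fell into this class there. The 2-fold rule counted monocyte-like 103 higher and 30 lower, B-cell-like 8 lower and plasma-like 39 lower genes. The T-cell-like cell cycle median was −0.11 and 0.79. Monocyte-like medians were uPAR 1.20 at week 12, stress −0.25 and −0.57, lipid and scar 2.09 and 2.43, cytokine 0.15 and −0.0213, and MHC class II 0.0708 and 1.26.

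Depth limits the shares of cells with Plaur. Thinned to 1000 UMIs they were 9.22% in chow and 8.54% in MASH at 12 weeks, and 6.88% and 7.05% at 24 weeks. Without neutrophil-like, hepatocyte-like, erythroid-like, mixed and unnamed cells they were 17.8%, 21.4%, 11.8% and 17.0%. The Plaur ratio over the remaining cells was 0.866 at week 12.

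With cells weighted equally, Plaur was 0.950 over all kept cells and 0.639 in stellate-like cells at week 12. T-cell-like medians were cell cycle −0.37 and 0.41, stress 0.21 at week 24, activation 0.70 at week 12, and naive and central memory 0.26 at week 24. Endothelial-like interferon was 0.53 and 0.79, and capillarisation turned to −0.0113 at week 12. Neutrophil-like cell cycle was −0.38 and 0.94 and stress 0.44 and −0.56, with Pclaf at 0.717 at week 12. Monocyte-like stress was −0.0812 and senescence −0.22 at week 24. Cluster 11 gave interferon −0.64 and stress −0.11 at week 24, lipid and scar 1.58 and 1.46, MHC class II −0.71 and 0.0298, and oxidative stress 0.51 at week 12. The stellate-like matrix median was 0.0842 at week 12.

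Scaled by TMM factors, Plaur was 0.929 over all kept cells and 0.724 in neutrophil-like cells at week 24, and 13 genes were lower in cluster 11 at both weeks. Stress medians were 0.34 in T-cell-like and −0.0501 in endothelial-like cells at week 12, 0.48 and −0.82 in neutrophil-like cells, −0.17 in monocyte-like cells at week 24 and −0.50 in cluster 11 at week 12. MHC class II in cluster 11 was −0.61 and oxidative stress 1.43 at week 12. With totals that leave out mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, B-cell-like 4, T-cell-like 32, NK-like 12 and plasmacytoid dendritic-like 1 genes were higher.

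Lowering the gene minimum to 10 UMIs and dropping the CPM minimum together lets in genes with few counts, and so can only add to the counts. They were B-cell-like 76 higher and 90 lower, T-cell-like 219 and 116, NK-like 63 and 61, hepatocyte-like 146 and 117, endothelial-like 73 and 108, and neutrophil-like 109 and 20. Monocyte-like cells had 94 and 33, conventional dendritic-like 131 and 50, plasmacytoid dendritic-like 22 and 66, plasma-like 187 and 208, and cluster 11 549 and 64. A minimum of 100 UMIs, with fewer genes compared, left NK-like 6 lower, hepatocyte-like 31 higher and 23 lower, endothelial-like 17 higher and 7 lower, neutrophil-like 4 higher and 0 lower, and monocyte-like 0 lower. It left conventional dendritic-like 3 lower, plasmacytoid dendritic-like 3 lower, plasma-like 36 higher and 25 lower, and cluster 11 5 lower.

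In single-hashtag cells, shares gave T-cell-like 0.842 at week 12, hepatocyte-like 0.516 and 0.499, endothelial-like 0.946 at week 12, and monocyte-like 1.55 and 2.92. Cluster 11 came to 17.96 at week 24, plasma-like cells to 0.422 and 0.436, stellate-like cells to 4.82 and 20.6, and basophil- or mast-like cells turned to 0.940 at week 12. Of 24-week MASH cells 17.3% had Plaur. Plaur ratios at week 24 were 0.961 over all kept cells, hepatocyte-like 0.401, conventional dendritic-like 0.577 and stellate-like 1.76, and plasma-like 0.452 and 0.462 at the 2 weeks. The 2-fold rule counted T-cell-like 11 lower, monocyte-like 17 higher and 3 lower, plasmacytoid dendritic-like 6 lower and plasma-like 18 higher genes. T-cell-like medians at week 24 were cell cycle 0.0968 and stress 0.21, and neutrophil-like cell cycle was 1.38. Monocyte-like medians were stress −0.19 and lipid and scar 0.37 at week 24, and MHC class II 0.22 and 1.09. Cluster 11 gave interferon −1.16 and stress −0.61 at week 12, lipid and scar 2.26 and 2.22, senescence −0.40 and MHC class II 0.23 at week 24, and oxidative stress 1.44 at week 12. The stellate-like matrix median was 0.75 at week 12, and Gsn turned to 1.27 at week 24.

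Shares of immune, endothelial and ductal classes alone gave B-cell-like 0.890 and 0.730, T-cell-like 0.802 and 0.803, NK-like 1.12 and 0.986, endothelial-like 0.763 at week 12 and neutrophil-like 1.085 at week 24.

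The splits of 24-week chow by hashtag set tagged chow cells against all MASH cells. Classes with many cells without a hashtag (hepatocyte-like 57.7%, basophil- or mast-like 38.4%, stellate-like 28.2%) thus shrink in chow by construction. Against hashtags 1 to 4, shares gave B-cell-like 0.645, NK-like 0.846, hepatocyte-like 0.639, endothelial-like 1.09, neutrophil-like 4.804, plasmacytoid dendritic-like 1.22, plasma-like 1.22, stellate-like 13.7 and basophil- or mast-like 1.51. Plaur was 1.14 over all kept cells, 0.726 in neutrophil-like and 0.624 in plasmacytoid dendritic-like cells. The 2-fold rule counted T-cell-like 10, endothelial-like 6, conventional dendritic-like 3, plasma-like 18 and cluster 11 11 lower, and plasmacytoid dendritic-like 1 higher and 2 lower genes. T-cell-like medians were cell cycle −0.14, stress 0.42, activation 0.82, and naive and central memory 0.15. Endothelial-like ones were interferon 0.71, stress −0.0416, sinusoidal identity −0.12 and capillarisation 0.54, and neutrophil-like ones cell cycle 2.48 and stress −0.60. Monocyte-like medians were uPAR −0.31, stress −0.0787 and cholesterol 0.0223. Conventional dendritic-like interferon was 0.30, cluster 11 had lipid and scar 2.25 and MHC class II 0.17, and stellate-like Gsn turned to 2.03.

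Against hashtags 5 to 8, shares gave B-cell-like 0.945, T-cell-like 0.7, NK-like 1.49, hepatocyte-like 1.70, endothelial-like 0.675, neutrophil-like 0.590 and cluster 11 37.5. Conventional dendritic-like cells came to 2.75, plasmacytoid dendritic-like 0.742, cholangiocyte-like 110, stellate-like 46.4 and basophil- or mast-like 1.40. Plaur was 0.841 over all kept cells, T-cell-like 4.13, NK-like 2.13, endothelial-like 1.90, conventional dendritic-like 1.10, cluster 11 0.889 and cholangiocyte-like 0.187. The 2-fold rule counted T-cell-like 29 higher, monocyte-like 22 higher and 1 lower, plasmacytoid dendritic-like 1 higher and 5 lower genes. Lower genes were NK-like 5, hepatocyte-like 19, endothelial-like 12, plasma-like 21 and cluster 11 4. T-cell-like medians were cell cycle 0.73, stress 0.0332 and activation 1.75. Endothelial-like medians were sinusoidal identity −0.35 and capillarisation 0.0698, neutrophil-like ones cell cycle 1.48 and stress −0.59. Monocyte-like ones were stress −0.18, MHC class II 1.29 and cholesterol −0.52, and conventional dendritic-like interferon was 1.49. Cluster 11 gave interferon −0.0695, stress −0.21, senescence −0.54, MHC class II −0.27 and oxidative stress 0.77, with Isg15 turned to 7.51 and Plac8 to 1.64. The stellate-like matrix median turned to −0.00966.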

Other observations

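The values of single hashtags were chosen for report after the data were seen, and no explanation was tested for them. Within 24-week chow the hashtags fell into 2 sets. Cells with hashtags 1 to 4 had 43.0% to 47.3% B-cell-like cells and 65.8 to 73.4 Plaur CPM, and cells with hashtags 5 to 8 had 29.9% to 32.2% and 84.4 to 100 CPM. In 24-week MASH the same sets had 4.41% to 5.34% and 7.11% to 8.13% of cells in cluster 11, and Pdcd1 in T-cell-like cells was 18.0 to 37.3 CPM and 50.4 to 63.2 CPM. The labels do not say whether a hashtag marks an animal, so these sets were not used as replicates.

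Plasmacytoid dendritic-like cells had 0 genes at least 2-fold higher and 12 at least 2-fold lower in MASH at both weeks, of 5653 compared, with 9 genes at least 2-fold in opposite directions. Independent lists would share 0.0619 and 0.360, and 11 of the 12 are open to RNA of other cells. In a run with no doublet removal 8 were higher and 6 lower, and only 3 were lower at a minimum of 100 UMIs and 2 against hashtags 1 to 4. Plasma-like cells had 95 higher, 78 lower and 27 opposite, of 5394, where independent lists would share 7.67 and 10.4, and 48 of the higher and lower ones are open to RNA of other cells. Single-hashtag cells gave 18 higher, a minimum of 100 UMIs 36 higher and 25 lower, resolution 0.5 39 lower, and hashtags 1 to 4 or 5 to 8 of chow 18 or 21 lower. Groups with under 100 cells in a library were counted apart: cluster 11 had 140 higher and 21 lower genes (137 higher without genes whose bound at 0 chow UMIs is under 2-fold), where independent lists would share 38.8 and 3.36. Stellate-like cells had 170 (152 by the same rule) and 20, against 69.9 and 1.35, and cholangiocyte-like cells 303 and 165, against 93.2 and 12.1. At a minimum of 100 UMIs these became 5 lower in cluster 11, 87 and 6 in stellate-like cells and 147 and 44 in cholangiocyte-like cells. Stellate-like cells had 90 lower with no doublet removal, and against hashtags 5 to 8 cholangiocyte-like cells had 14 lower.

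In stellate-like cells 2 genes with 0 chow UMIs, chosen after their values were seen, were higher at both weeks. Chil1 was at least 15.7-fold and at least 23.5-fold higher and Sprr1a at least 7.30-fold and at least 30.4-fold higher. Endothelial-like cells showed genes that turned between the weeks, such as Sele at 3.54 (1.42 to 10.6) and 0.0918 (0.0406 to 0.182), and Apln at 0.131 (0.0536 to 0.277) and 3.50 (1.77 to 7.55). In neutrophil-like cells Mki67 was at 1.36 (0.852 to 2.25) and 16.1 (9.07 to 31.5), or 0.281 and 1.05 with no doublet removal.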
